A study of Macaca mulatta with 8 samples.

How the data were processed

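Total RNA of 2 neocortical areas of the rhesus macaque, M1 and A46, was measured on Agilent single-colour (Cy3) arrays, 4 per area. Per the labels, RNA was reverse transcribed with an oligo(dT) primer and amplified as labelled complementary RNA. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 under a single-colour protocol, and the probes were designed on the rheMac2 build. The deposited scanner files give for each spot an intensity in linear scanner units that had been background-subtracted and detrended within the array, per the file headers, and had not been normalized between arrays. The authors' deposited series table gives log2 values for the same arrays. Differences between pairs of its columns followed the scanner values with a slope of 1 and r = 1.000 and differed from them by a median of at most 0.0091 log2 units after the 75th percentile shift, which sets their scale, shift and direction. The medians of its columns lay between -0.06 and 0.09, and the baseline on which each probe was centred is not given in the sources used here. How the deposited log2 values were made is otherwise not given in the sources used here.

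Each array carried 41851 spots, of which 1417 were control spots and were left out. Spots called outliers by the scanner software were left out, 0 to 220 per array, and no spot was saturated. The log2 processed intensity was averaged over the 2 spots of a probe, and the 75th percentile of each array was subtracted. Probes well above background on all 4 arrays of at least 1 area were tested, 14698 of 20217. The fit was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, area as the only term, 6 residual degrees of freedom), with Benjamini-Hochberg adjustment over all tested probes at 0.05. Tables were read with Python 3.11.15 and pandas 2.3.3. The number of arrays limits the precision, the median SE of a difference being 0.18 log2 units, or 0.11 with the replicate block.

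The files name probes by transcript identifiers and give no gene names. RefSeq identifiers were matched without versions to a gene table of the assembly T2T-MMU8v2.0, used for names only. Of 5583 probes with a RefSeq identifier, 942 matched, of which 44 carried only a locus number and 898 a gene name, for 835 genes. The 9769 probes with an Ensembl transcript, 367 with a GenBank identifier and 4498 with a probe name alone were not named here. Of the named genes, 547 were tested. Where several probes stood for a gene, the brightest was used. No probe of a gene named here passed in the direction opposite to that gene's. No genome coordinates are given, since the assemblies differ.

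No label ties a replicate number to an animal, although per the labels 4 animals gave both areas. The numbers were therefore checked. Deviations from the area mean over the tested probes correlated between the arrays of the same number with r = 0.726, 0.634, 0.166 and 0.858 for numbers 1 to 4, each over the 0.1 set beforehand, across probes that are not independent replicates. A46 replicate 3 correlated more closely with M1 replicate 4 (r = 0.483), scanned like it on a later day. A46 replicate 2 and M1 replicate 3, of unlike numbers but scanned on the same day, were also over 0.1 (r = 0.262). The cut-off by itself therefore does not tell a shared number from shared scanning. Blocked values, from a fit with the replicate number as a fixed term (3 residual degrees of freedom), stand beside a result where they change the call or the count. Whether same-numbered samples came from 1 animal rests on this check, and without it p-values measure the spread between the samples of an area.

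The tests, 33 gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule takes up to 10 genes in each direction past the threshold that were well above background on all 8 arrays without overlap between the areas, and for each list the tested member with the smallest p, or 3 where the list passes or has at least 2 called members. It also named 14 landmark genes, none of which could be matched to a probe, and genes detected in 1 area alone, of which none with a name passed in either fit. After the results were seen, the first part of the rule was applied to the blocked fit as well, with the same sign in all 4 pairs in place of no overlap. Other members of lists are named after their values were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Alternatives were normexp background correction with an offset of 50, quantile and median normalization, the deposited values, other filters, array weights, an intensity trend, fixed and random blocks, the mean of the tested myelin genes as a covariate, and leaving out each array. Normexp was run on the median spot and background signals, and the mean spot signal was not used here. Alternatives with the scan day and the later scans, and 8 further gene lists, were added after the data were seen, as was the count of probes without overlap under other splits.

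The steps were tested on simulated data with the means and spreads of 14683 probes, 10 simulations and 200 changed probes in each. For M1 against A46, 55.1% of the probes changed by a log2 of 1 and 89.4% of those changed by a log2 of 2 were recovered, with 1.23% false calls, and with the replicate block 68.9%, 93.1% and 4.31%. Noise and replicate effects were drawn independently for each probe, and no set of later scans was simulated. The shares of recovered probes and false calls therefore need not carry over to the real arrays. For lists of 5 genes among 562, camera called 7% of unchanged lists and 100% of lists shifted by a log2 of 1. These lists were simulated with independent genes and only the spread left after the replicate block. Their shares therefore do not carry over to the real lists, whose genes may vary together and whose unblocked spread is larger. Arrays with the same replicate number, slide or scan day were taken from the labels and file headers.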

Results

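Gene expression was compared between 2 areas of the rhesus macaque neocortex: the primary motor cortex (M1), which drives voluntary movement, and area 46 (A46), a prefrontal association area. The question, as the series title gives it, was which genes differ in expression between a motor and a prefrontal association area. Tissue was dissected from the left hemisphere of 4 adolescent animals, from the forelimb part of M1 and from the banks of the principal sulcus for A46. Each area was measured on 4 single-colour oligonucleotide arrays, numbered 1 to 4 within the area. Each array carried 20217 probes at 2 spots each. Between 71.4% and 77.3% of the probes were well above background on an array, and the 75th percentile of the signal lay between 1234 and 2008 scanner units. The median negative control spot lay between 1.11 and 4.90 units. The number of arrays limited the precision. Levels are given below in log2 units relative to the 75th percentile of the array, and differences are M1 minus A46. A symbol was matched to 942 of the 20217 probes (4.66%), 898 with a gene name and 44 with only a locus number. Most of the differences below therefore belong to probes without a name.

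The named genes that separated the areas most clearly were SLPI, higher in M1, and EPHA3 and TYR, higher in A46. SLPI, which encodes a secreted inhibitor of serine proteases, was 3.63-fold higher in M1, at -4.09 ± 0.33 (SD, n = 4) against -5.95 ± 0.14 in A46 (log2 difference 1.86 ± 0.18 SE, limma adjusted p = 0.0332). EPHA3, a receptor tyrosine kinase for ephrin-A ligands with a role in axon guidance, stood at -2.06 ± 0.30 in M1 and -0.71 ± 0.19 in A46 (log2 difference -1.35 ± 0.17 SE, adjusted p = 0.0332). TYR, tyrosinase, the rate-limiting enzyme of melanin synthesis, stood at -6.47 ± 0.31 in M1 and -4.48 ± 0.50 in A46 (log2 difference -1.99 ± 0.26 SE, adjusted p = 0.0358). The probes of these genes were A_01_P005468 for SLPI, A_01_P016237 for EPHA3 and A_01_P008096 for TYR. Their values did not overlap between the areas, as the rule that named them required. The sign was therefore bound to be the same in 4 of 4 same-numbered pairs. After a normexp background correction SLPI stood at 0.90 (adjusted p = 0.0482), and TYR at -0.72, which did not pass (adjusted p = 0.170; 0.0225 with the block), and TYR also missed the threshold with quantile normalization (-1.92, adjusted p = 0.0510). The normexp offset of 50 by itself shrinks the log2 differences of dim probes, such as those of SLPI and TYR. Over all fits the adjusted p ran from 0.00151 to 1.00 for SLPI and from 0.00291 to 1.00 for EPHA3 and TYR.

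Across the array, 27 of 14698 tested probes differed at an adjusted p under 0.05, 20 higher in M1 and 7 higher in A46, and 25 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1388 probes, where 734.9 would be expected by chance. With the replicate number as a block, 380 probes passed, 237 higher in M1 and 143 higher in A46, and 117 of them by at least 2-fold. The block rests on the correlation between same-numbered arrays, which some arrays of unlike numbers also showed. All 27 probes were among the 380. The areas did not overlap in any of the 27 probes. Over all tested probes, 949 (6.46%) showed no overlap, against 2.86% if the 8 arrays were interchangeable, which the pairs and the scan sets do not allow. Of the 35 splits of the arrays into 4 and 4, 6 gave as many, the real one included, with up to 12.1%, and the 7 others that part all 4 pairs gave 0.204% to 0.694%. Among the probes without a name, A_01_P017383 (log2 difference 1.91 ± 0.19 SE) and A_01_P018104 (1.60 ± 0.18 SE) were higher in M1, and A_01_P004422 (-2.32 ± 0.25 SE) and A_01_P002915 (-1.74 ± 0.19 SE) were higher in A46, each with an adjusted p of 0.0332. Without A46 replicate 1, 2, 3 or 4, or M1 replicate 1, 2 or 3, the limma count was 0, with 975 to 1429 probes at an unadjusted p under 0.05, and without M1 replicate 4 it was 4. It was also 0 with no filter on dim probes (1371 at an unadjusted p under 0.05) and with the mean of UGT8 and TSPAN2 as a covariate (433), where EPHA3 stood at -0.61. The sign of all 27 differences was the same in each of these fits. Since the areas did not overlap in these probes, leaving out an array could not turn it. UGT8 did not overlap between the areas (A46 -4.02 to -3.35, M1 -2.28 to -1.14), so its mean with TSPAN2 largely follows the area. Here and below, fits with this covariate cannot tell an effect of myelin content from one of area.

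With the replicate block, 21 named genes passed. Among those higher in M1 were UGT8 and ZNF488, both known from oligodendrocytes, the myelin-forming cells. UGT8, which makes galactocerebroside, a main lipid of myelin, was 3.12-fold higher in M1, at -1.96 ± 0.55 (SD, n = 4) against -3.60 ± 0.29 (log2 difference 1.64 ± 0.19 blocked SE, blocked adjusted p = 0.0287; 0.0624 without the block). ZNF488, a transcriptional regulator of oligodendrocyte differentiation, was 2.58-fold higher in M1 (log2 difference 1.37 ± 0.21 blocked SE, blocked adjusted p = 0.0391; 0.0841 without the block). MOSPD2, a protein of membrane contact sites, was higher by 1.04 ± 0.11 and ANGPTL2, a secreted glycoprotein, by 0.93 ± 0.12. SELENOP, the selenium transport protein, was higher by 0.66 ± 0.11, SCARB2, a lysosomal membrane protein, by 0.64 ± 0.10, the kinase gene MAK by 0.57 ± 0.10, and EDIL3, a secreted integrin ligand, by 0.51 ± 0.08 (log2 differences ± blocked SE). The blocked adjusted p of these 6 genes, from MOSPD2 to EDIL3, was 0.0287 to 0.0474, and without the block it was 0.103 to 0.656. After normexp ZNF488 stood at 0.44 (blocked adjusted p = 0.0417), ANGPTL2 at 0.43 (0.0605) and MAK at 0.32 (0.0905), and MAK also missed the threshold in the blocked fit with quantile normalization (0.0583) and with an intensity trend (0.0574). With the mean of UGT8 and TSPAN2 as a covariate in place of the block, MOSPD2 stood at 0.49, ZNF488 at 0.36, SELENOP at 0.32, ANGPTL2 at 0.31, EDIL3 at 0.26, SCARB2 at 0.17 and MAK at 1.43.

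Among the named genes higher in A46 with the block were the receptor genes GRIK1 and CRHR1. GRIK1, a kainate receptor subunit, stood at 0.01 ± 0.29 (SD, n = 4) in A46 and -0.72 ± 0.30 in M1 (log2 difference -0.72 ± 0.10 blocked SE, blocked adjusted p = 0.0366; 0.247 without the block). CRHR1, the receptor of corticotropin-releasing hormone, stood at 2.32 ± 0.12 in A46 and 1.76 ± 0.20 in M1 (log2 difference -0.56 ± 0.08 blocked SE, blocked adjusted p = 0.0382; 0.177 without the block). MYOT, which encodes a sarcomere protein, differed by -0.80 ± 0.13, and ACKR1, a chemokine-binding receptor of venous endothelium, by -0.66 ± 0.11 (blocked adjusted p = 0.0450 and 0.0473; 0.637 and 0.430 without the block), and after normexp they stood at -0.37 and -0.56 and missed the threshold (blocked adjusted p = 0.0603 and 0.0619). With the mean of UGT8 and TSPAN2 as a covariate in place of the block, GRIK1 stood at -0.13, CRHR1 at -0.038 and MYOT at -2.19, and without M1 replicate 3 MYOT stood at -0.45. The fit with this covariate, which largely follows the area, does not show that myelin content accounts for these differences. DOCK5 (1.36), SERPINC1 (0.47) and CD101 (-0.59) also passed with the block, each well above background on 3 of the 4 arrays of one area, and are named here after their values were seen. Also among the 380 were 3 probes without a name that were well above background on all 4 arrays of one area and on none of the other. Against the lowest signal well above background on each array, or the probe's own where higher, 2 of them were at least 4.54-fold and at least 1.98-fold higher in A46 (blocked adjusted p = 0.0287 for both; 0.0956 and 0.0586 without the block), and 1 was at least 1.42-fold higher in M1 (0.0450; 0.286 without the block). The blocked count was 2 without the pair of replicate 1, 0 without that of replicate 2 (2399 at an unadjusted p under 0.05) and 1 without that of replicate 4, but 405 without that of replicate 3, and it was 0 with no filter on dim probes (2955). With the later scans as a further covariate it was 403, and ZNF488 (adjusted p = 0.0521), SCARB2 (0.0512), MAK (0.0558), ACKR1 (0.0682), MYOT (0.0646) and IDI1 (0.0639) then missed the threshold. That covariate leaves the difference to the pairs numbered 1, 2 and 4. Apart from the probes tested, this fit therefore repeats the one without the pair of replicate 3.

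**Figure D1:**
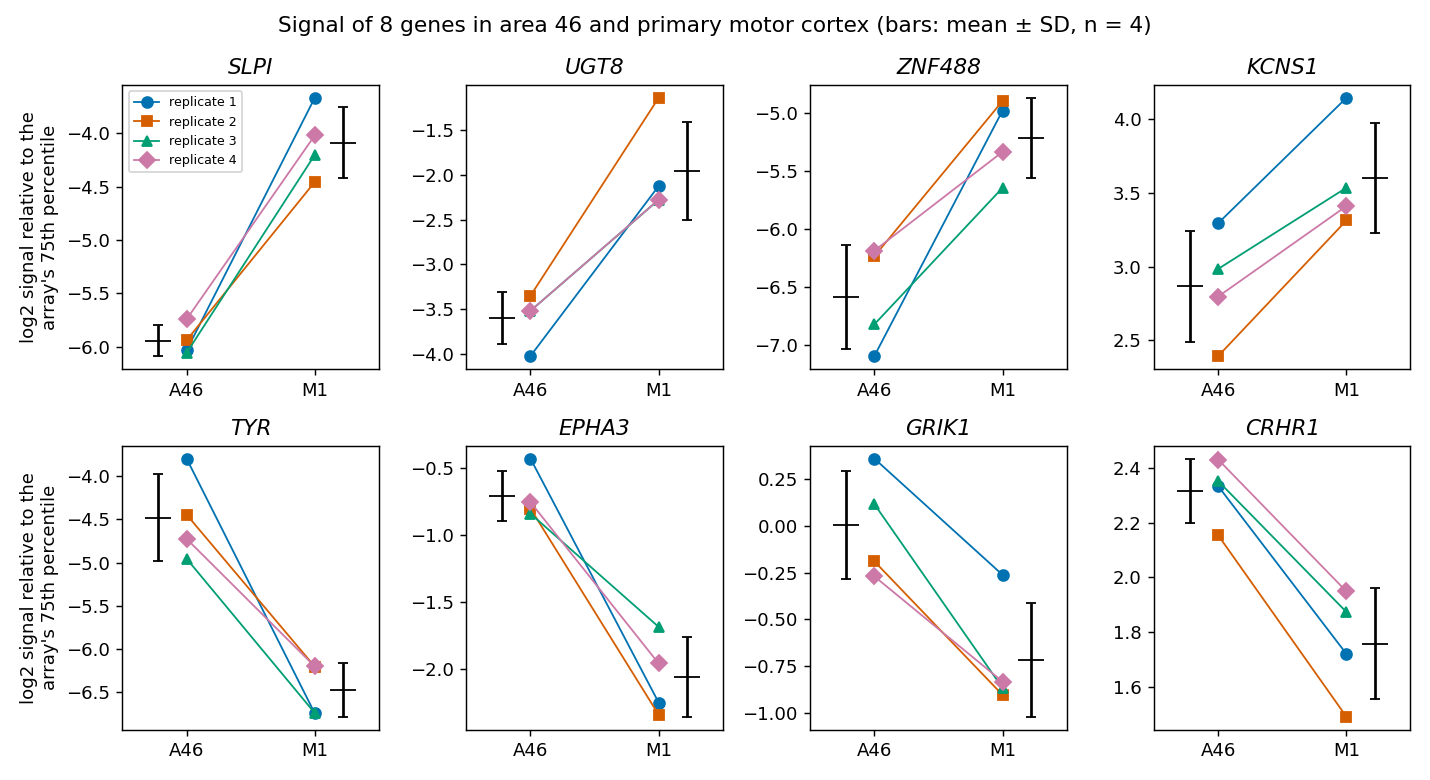
Signal of SLPI, UGT8, ZNF488, KCNS1, TYR, EPHA3, GRIK1 and CRHR1 on each array, in log2 units relative to the 75th percentile of the array, for A46 and M1. Coloured lines join arrays of the same replicate number (replicates 3 and 4 overlie each other for UGT8), and black bars give the mean ± SD of 4 arrays. Each gene moves the same way in all 4 pairs, which the rule for naming genes in the blocked fit required.

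Gene groups fixed before the data were examined could be read only in part, since 36 of their 719 genes were named and tested. Of the 33 lists, 13 had no tested member, 19 had 1 to 4, and 1 had the 5 needed for a set test. EPHA3 was the only list gene past the threshold without the block, and UGT8, EPHA3, KCNS1, GRIK1, TSHZ3 and IDI1 passed with it. Both tested members of the myelin and oligodendrocyte list were higher in M1 when adjusted over the list alone, UGT8 and the tetraspanin gene TSPAN2 (log2 difference 0.38 ± 0.11 SE, adjusted p = 0.287 over all probes, 0.111 with the block). In the axon guidance list, EPHA3 passed over all probes, while its ligand EFNA1 stood at 0.59 ± 0.19 SE (adjusted p = 0.338), PLXNA1 at -0.36 ± 0.25 SE and EPHB1 at 0.01 ± 0.16 SE. Adjusted over the list alone, EFNA1 and EPHA3 passed, and with the block PLXNA1 did too.

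Potassium channel genes went both ways. KCNS1, a silent subunit that modifies other channels, was 1.66-fold higher in M1 with the block (log2 difference 0.73 ± 0.10 blocked SE, blocked adjusted p = 0.0340; 0.341 without the block; log2 difference 1.64 with the mean of UGT8 and TSPAN2 as a covariate in place of it), and it was also the only tested member of the parvalbumin and fast-spiking interneuron list. KCNA4 stood at -0.50 ± 0.12 SE (adjusted p = 0.191; 0.0950 with the block), KCNC4 at -0.34 ± 0.19 SE, KCNA5 at -0.22 ± 0.17 SE and KCNA6 at 0.32 ± 0.23 SE. Adjusted over the list alone, 1 member passed in each direction, and with the block 2 in each. The list as a whole did not pass (camera p = 0.454, median -0.22, 2 members above 0 and 3 below; p = 0.474 with an estimated correlation and 0.879 with the block). By fry, which asks whether the members move 1 way on balance, p was 0.205, and 0.0311, under 0.05, with the block. The mean difference of the members was -0.0022, so no clear direction follows. By the mixed test of fry, which asks whether members move in either direction, p was 0.00595, and 0.00159 with the block. This test does not compare the members with other genes. With the block, 3126 of all 14698 tested probes had an unadjusted limma p under 0.05, where 734.9 would be expected by chance. The mixed test therefore does not set potassium channels apart from other genes.

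Smaller groups held 1 or 2 tested genes each. TSHZ3, of the cortical patterning transcription factors, was lower in M1 with the block (log2 difference -0.61 ± 0.08 blocked SE, blocked adjusted p = 0.0312; 0.356 without the block), beside BHLHE22 at -0.42 ± 0.21 SE (adjusted p = 0.605), which passed only with the block and adjusted over the list alone. Of the ionotropic glutamate receptors, GRIK1 passed with the block and GRIK3 stood at 0.10 ± 0.23 SE. Of cholesterol synthesis, the isomerase gene IDI1 was higher in M1 with the block (log2 difference 0.49 ± 0.08 blocked SE, blocked adjusted p = 0.0486, or 0.0566 with quantile normalization; 0.577 without the block). With the mean of UGT8 and TSPAN2 as a covariate in place of the block, TSHZ3 stood at -1.10 and IDI1 at 0.11, and without A46 replicate 1 IDI1 stood at 0.32.

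In the other 13 lists with a tested member no gene passed in either fit. The member with the smallest p in each of them lay between -0.36 (PLXNA1, of the known area-selective genes) and 0.35 (MATN4, of the extracellular matrix and perineuronal net), with adjusted p from 0.695 to 0.979. Between them lay FGFR3 of astrocytes (-0.05), S100A10 of layer 5 neurons (-0.06), HBE1 of blood (-0.07), GABRA5 of the GABA receptors (-0.12), STMN1 of the axonal cytoskeleton (-0.14), RXRB of retinoic acid signalling (-0.21), COX5A of oxidative phosphorylation (-0.30), EGR4 of the immediate early genes (-0.33), ADRA1B of the monoamine and acetylcholine receptors (0.32) and HSPA1L of the heat shock genes (0.22). With the block, adjusted over the list alone, MATN4 (higher in M1) and HAS3 (higher in A46) passed in opposite directions. PLXNA1 was the only tested member of its list here, so that its unadjusted blocked limma p of 0.00815 stood for the list (adjusted p = 0.103 over all probes). The markers of blood and of astrocytes rested on 1 gene each and allow no statement on the makeup of the tissue.

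The scan days gave a further split of the arrays, which A46 and M1 shared unequally: A46 replicates 3 and 4 and M1 replicate 4 were scanned on the 2 later days, on 3 slides of their own. These 3 arrays scored 37.0 to 44.8 on the first principal component, which held 48.4% of the variance, and the other 5 arrays scored -37.4 to -16.6. COX5A lay at 3.71 to 3.83 on the 3 arrays and at 2.32 to 2.50 on the other 5. The arrays numbered 1, 2 and 4 were scanned on the same day in both areas, and those numbered 1 also shared a slide. In the pairs numbered 1, 2 and 4, SLPI differed by 2.37, 1.49 and 1.73, EPHA3 by -1.82, -1.54 and -1.20, TYR by -2.95, -1.76 and -1.48, and UGT8 by 1.89, 2.21 and 1.24. The signs were fixed beforehand, since these genes did not overlap between the areas. With the scan day as a fixed block, 153 probes passed, 24 of them among the 27, and EPHA3 missed the threshold (adjusted p = 0.0506). With it as a random block, 722 passed.

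**Figure D2:**
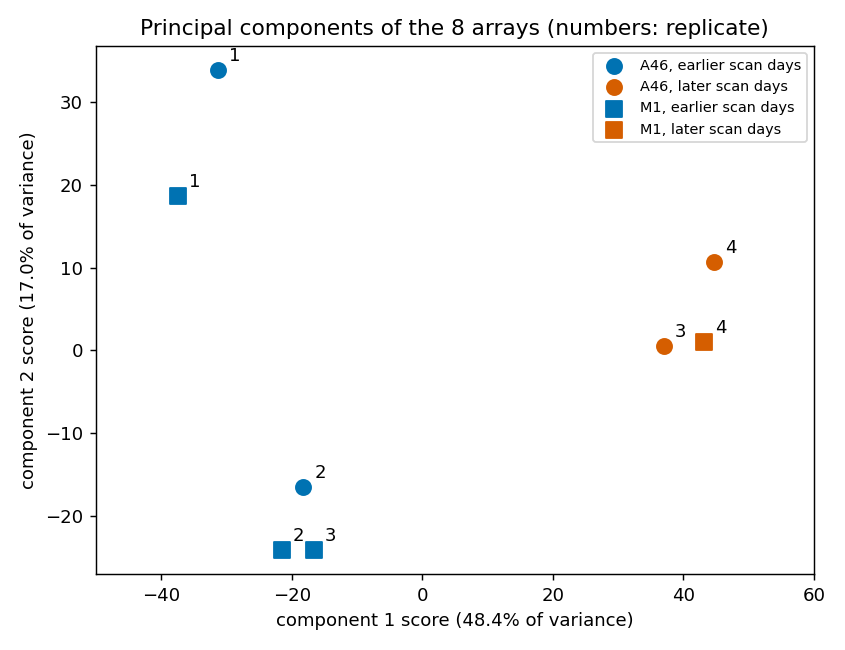
Scores of the 8 arrays on principal components 1 (48.4% of the variance) and 2 (17.0%), computed from the tested probes, with circles for A46, squares for M1 and the replicate number beside each point. The 3 arrays of the later scan days (orange) lie at 37.0 to 44.8 on component 1, and the 5 arrays of the earlier days (blue) lie below 0.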

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

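Of the tests in this part, those of the shared slide or day and of the animal behind the pairing, and those of the animals and of the scan batch behind the 3 later arrays, were chosen after the results were seen. The test of the background level and the counts of other splits were set beforehand.

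In 10 of 74 groups of 4 arrays, 1 array lay far from the other 3, where chance gives about 3.7. In A46 these were replicate 1 for IDI1 (-2.01, others -1.37 to -1.25), replicate 3 for HSPA1L (-2.75, others -3.83 to -3.65) and replicate 1 for spots called outliers (220, others 0 to 4). In M1 they were replicate 2 for UGT8 (-1.14, others -2.28 to -2.13), replicate 3 for HSPA1L (-2.72, others -3.50 to -3.39), replicate 1 for GRIK1 (-0.26, others -0.90 to -0.83) and replicate 1 for outlier spots (147, others 2 to 3). M1 replicate 4 stood apart for COX5A (3.80, others 2.32 to 2.50), for ACKR1 (1.54, others 0.61 to 0.69) and for the negative control signal (4.90 units, others 1.22 to 1.35). HSPA1L stood apart in replicate 3 of both areas, and the 2 arrays with many outlier spots shared a slide.

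The 3 arrays of the later scans, A46 replicates 3 and 4 and M1 replicate 4, stood apart from the other 5, with 3138 probes past an adjusted p of 0.05 between the sets. A difference between animals 3 and 4 and animals 1 and 2 would place M1 replicate 3 with them, and it scored -16.6 on the first component, on the side of the other 5. This stays open, since it rests on 1 array and on number 3 marking 1 animal in both areas. A higher background would move dim probes alone, but 40 probes well above background on all 8 arrays separated the 3 arrays by over 2 log2 units, and the next of 56 sets of 3 arrays gave 0. The scan or slide set placed 8 of 8 arrays on the right side, so that a batch of slides or scans is a candidate explanation, found and tested on the same arrays. Which step of the laboratory work it reflects was not tested.

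Arrays with the same replicate number deviated alike, most for numbers 1, 2 and 4, which shared a scan day. In 41 probes the arrays of both areas fell into high and low sets more than 3 log2 units apart, and 28 of these fell alike by replicate number, against at most 17 under the other 23 pairings of the numbers (exact p = 0.0417, the smallest that 24 pairings allow). A shared slide or day would leave number 3 unpaired, but of 3 probes in which A46 replicate 3 alone stood apart, M1 replicate 3, of another day and slide, was the most extreme M1 array in 100% (exact 95% interval 29.2% to 100%, chance 25%), which rests on 3 probes. The interval counts probes of the same arrays as independent, which they need not be, so that it cannot exclude a shared slide or day. M1 replicate 2 was the most extreme M1 array in 100% of the 6 probes in which A46 replicate 2 stood apart, although M1 replicate 3 was scanned on the same day, and so the numbers may mark animals. All 13 probes that fell differently did so in replicate 3 alone, and in 12 of these the 2 later A46 arrays lay with M1 replicate 4 and M1 replicate 3 with the arrays of the earlier scans.

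Other splits of the 8 arrays into 4 and 4 tell how far chance can be excluded. Of 35 splits, 2 gave as many probes as the 27 between M1 and A46, the real one included, so that chance was not excluded by this count, and likewise 2 gave as many as the 25 probes of at least 2-fold. The other split set replicates 1 and 2 against replicates 3 and 4, with 136 probes and 75 of at least 2-fold, several times the real count, and it follows the pairs and all but 1 array of the scan sets, which points to that structure of the samples. The real split parts all 4 pairs, as 7 others do, and each of those 7 gave 0 probes. With the replicate block, 1 of the 8 ways to swap the areas within pairs gave as many as 380, the real one, and the highest other gave 0. The 8 swaps are too few for a share under 0.05.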

How the results depend on the processing

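The fits with the scan day, with the later scans and without both arrays of replicate 3, and the variants of the blocked fit, were chosen after the data were seen. All 27 differences had the same sign in every fit, or 25 of the 25 that remained tested with the filter on all 8 arrays, but their adjusted p depended on the estimate of spread. Since the areas did not overlap in any of the 27, leaving out arrays or adding the replicate block could not turn a sign. Those fits are therefore no evidence for it. The counts moved as follows, in the order all probes, higher in M1, higher in A46 and at least 2-fold, with 27, 20, 7 and 25 as reported. Except where said, the cause was not tested.

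With the replicate block they were 380, 237, 143 and 117, and with a random replicate block 984, 557, 427 and 135. The block removes the spread between numbers, so that the median SE was 0.11 in place of 0.18. They were 138, 93, 45 and 79 with array weights, 153, 96, 57 and 71 with the scan day as a fixed block, 722, 412, 310 and 132 with it as a random block, 71, 46, 25 and 43 with the later scans as a covariate, and 403, 252, 151 and 152 with the replicate block and the later scans. The last of these fits takes its differences from the same pairs as the blocked fit without replicate 3. Normexp gave 41 probes, 32 of them higher in M1, normexp with quantile normalization 48, 36 and 12, and an intensity trend 43 and 33, with 38 of at least 2-fold. Each was 0, 0, 0 and 0 with no filter on dim probes, with the myelin covariate and without both arrays of replicate 3 (882 probes at an unadjusted p under 0.05), and 0 probes passed at an adjusted p under 0.01. Leaving out 1 array at a time, with fewer samples, gave 0 to 4, 0 to 3, 0 to 1 and 0 to 4. Quantile and median normalization, the deposited values and the filter on all 8 arrays gave 24, 21, 27 and 25 probes, within 1.5 times of 27.

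The count of 380 with the replicate block was 0 with no filter, 996 with array weights, 632 with an intensity trend, and 0 to 405 without 1 pair (405 without replicate 3, 2, 0 and 1 without replicates 1, 2 and 4). All 380 kept their sign, but each had the same sign in all 4 pairs, so that leaving out a pair could not turn it. Camera on the potassium channel list stayed short of the threshold in every fit, and over all probes and in the lists set beforehand the block changed no other call than those given beside the results.

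Signs turned only in genes that passed in no fit, apart from UGT8 under the myelin covariate (-0.14), which UGT8 itself is part of. The same covariate gave 0.33 for S100A10 and 0.054 for GABRA5. HBE1, FGFR3 and COX5A turned with the scans: HBE1 to 0.23 and COX5A to 0.041 with a fixed scan day, HBE1 to 0.14 with a random one, FGFR3 to 0.0017, HBE1 to 0.17 and COX5A to 0.039 with the later scans, and FGFR3 to 0.0058, HBE1 to 0.28 and COX5A to 0.036 both with the block and the later scans and without replicate 3. Without 1 array, HBE1 ranged from -0.31 to 0.15, FGFR3 from -0.12 to 0.029, GABRA5 from -0.25 to 0.013, COX5A from -0.64 to -0.056 and S100A10 from -0.17 to 0.022. Normexp added an offset of 50 to every signal, which shrinks the log2 differences of dim genes whatever their background. The smaller differences after it, such as -0.72 for TYR, cannot tell how far background limits these genes. The slide as a block could not be fitted, since 1 slide held more than 1 array, the lists without shared genes left no list of 5, and random blocks give no camera value.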

Other observations

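The 8 gene lists here were written after named values had been seen, and the tests of oligodendrocyte RNA and of slides, and the t intervals, were chosen after their results were known. The test within scan days was set beforehand, but the oligodendrocyte list it used was not.

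All 8 genes of a list of oligodendrocyte genes lay above 0, with a median log2 difference of 0.51. They are no independent evidence of a direction, since 7 of the 8 were among the 70 names with the smallest p, from which the list was written. With the block UGT8, ZNF488, DOCK5 and EDIL3 passed over all probes. PLXNB3, a semaphorin receptor (0.51), SEPTIN8, a cytoskeletal GTPase gene (0.43), TSPAN2 (0.38) and GALC, which breaks down galactocerebroside (0.13), did not.

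The lists below were also written after named values had been seen, so that their tests are no independent evidence either. Of the genes of neuronal signalling, 17 of 24 lay below 0, with a median of -0.16 (camera adjusted p = 0.0549; 0.0194 with the block; adjusted p = 0.347 and 0.319 with an estimated correlation). GRIK1 and CRHR1 passed with the block, and NEURL1, a ubiquitin ligase gene, stood at -0.36. Of the interferon response genes, 9 of 11 lay above 0, with a median of 0.28 (adjusted p = 0.0806; 0.0194 with the block; adjusted p = 0.615 and 0.629 with an estimated correlation), but the mean difference was 0.73 in the pair of replicate 1 and 0.04 to 0.16 in the other 3. The threshold was not passed by astrocyte genes (adjusted p = 0.902), endothelial genes (0.383), microglia and leukocyte genes (0.685), selenoprotein genes (0.902, where SELENOP alone of 16 passed with the block) or zinc finger genes (0.902). Of the endothelial genes, EMCN (0.36) and APOLD1 (0.62) lay above 0 and ACKR1 (-0.66) below.

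Why the genes of the oligodendrocyte list lay above 0 was weighed between 3 explanations. A batch between scan days cannot part 2 arrays of 1 day. In each of the 3 pairs of 1 day the list's mean difference was at least 0.65. Its average over them was 0.85 (95% t interval 0.40 to 1.31, n = 3 pairs). The list cannot weigh against such a batch, since most of its genes were picked because they differed on these arrays. For UGT8 and TSPAN2, listed before the data were examined, the average over these pairs was 1.09 (0.45 to 1.74). That argues against such a batch as the whole cause for the mean of these 2 genes, which UGT8 carried (1.89, 2.21 and 1.24 in these pairs). TSPAN2 differed by 0.15, 0.56 and 0.51, and the average does not settle the question for TSPAN2 alone. With the later scans beside the block, COX5A went from -0.30 to 0.036. UGT8 at 1.78, DOCK5 at 1.45 and EDIL3 at 0.52 then passed the threshold, and ZNF488 at 1.43 missed it (adjusted p = 0.0521). That fit takes its differences from the same 3 pairs and adds no separate evidence. A batch between slides stays open, since only 1 pair shared a slide, with a difference of 1.00. More oligodendrocyte RNA in the M1 samples, from the cortex itself or from white matter taken with it, may account for the pattern. Camera gave an adjusted p of 1.3e-07 at the preset correlation (3.5e-06 with the block) and 0.0952 with an estimated one (0.231 with the block). By fry the adjusted p was 0.0151 (0.0241 with the block). These set tests do not decide it, since most of the genes were picked because they differed. A difference between the areas in the expression of these genes per cell stays open as well and was not tested.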
